A study of Oryza sativa with 12 samples.

How the data were processed

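RNA sequencing measured gene expression in leaf primordia of rice (Oryza sativa), starting from total RNA per the labels. How ribosomal RNA was removed is not given in the sources used here. Plants grew in a chamber with 15 h of light at 28 °C and 9 h of darkness at 24 °C, at 70% relative humidity, and 2 µg of total RNA per sample went into an NEBNext Ultra RNA library. The 12 libraries form 4 groups of 3: WT (the cultivar Nipponbare), ospin1c ospin1d, ospid C1 and ospid C2. Groups and replicate numbers were taken from the sample titles. The labels do not state whether replicates came from separate plants or pools, so p-values measure the spread between these samples, which may be technical.

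The authors deposited a table per library with an identifier and an FPKM value (fragment counts scaled by gene length and library size), per the file headers. The submitters' processing notes name Bowtie2 2.2.3, HISAT2 2.1.0, HTSeq 0.6.0 and the build IRGSP-1.0, without the role or order of each tool. All 12 tables list the same 32552 identifiers: 28962 starting with Os, 3584 starting with EPlOSAG and 6 starting with ENSRNA. Whether counting used strand, and how reads shared between near-identical genes were treated, is not given in the sources used here, so overlapping, antisense and duplicated genes may share reads.

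The depth was worked out from the steps between FPKM values, since 1 read adds a fixed amount that depends on gene length and depth. For WT replicate 1 a total was sought at which the implied gene lengths were whole numbers. The other depths followed from the commonest ratio of their FPKM values to that library among low genes. At the total found, 99.97% of the lengths of a subset of genes were whole within 0.05 bases, against 9.98% at the median of other totals tried. The depths were 15211547 to 16422849 reads, and the recovered gene reads summed to between 99.96% and 99.98% of them. For a gene of 1 kb, 1 read is worth 0.0609 to 0.0657 FPKM. Lengths given below come from the same steps. Each is the smallest whole length that gave whole reads in every library, so lengths and recovered reads are lower bounds. A multiple may fit as well for features read in few libraries.

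The design fixed before the data were examined was written for counts, with a test on FPKM as its stated fallback. Because the tables hold FPKM, the fallback was used: limma 3.58.1 in R 4.3.3 with a mean-dependent prior on log2(FPKM + 1), for genes at 1 FPKM or more in at least 3 libraries. This left 21250 genes. All 12 libraries entered 1 fit with a mean per group, no covariate, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Adjusted p values below are from this test unless another is named. Libraries listed at 0 add no spread to the fit. For identifiers at 0 in whole groups, these values may thus be too small. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The scaling by library size was kept as deposited. The 5 comparisons were each mutant line against WT, ospid C2 against ospid C1, and the mean of both ospid lines against ospin1c ospin1d.

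The test was first run on simulated data with the means and spread of the 21250 genes and 200 changed genes. For ospin1c ospin1d against WT it recovered 66.0% of changes of 1 on the log2 scale and 89.0% of changes of 2, with 9 false calls. For ospid C2 against ospid C1 it recovered 69.0% and 89.0%, with 6 false calls. These rates hold for 200 changed genes and noise independent between genes. Recovery may be lower where fewer genes change.

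Identifiers were looked up in a table of 39387 rice genes of the assembly ASM3414082v1, and 1 of 32552 matched. The deposited tables do not pair identifiers with names, so no gene names are given. For the same reason OsPIN1c, OsPIN1d and OsPID were not looked up, and the genotype labels were not checked against them. Of 95 identifiers written for gene sets fixed beforehand, 0 were among the deposited identifiers that matched the table of rice genes. The 95 were not matched to the deposited tables directly, and the sets were not tested. The named identifiers are, per comparison, at most 2 that rose and 2 that fell with the largest log2 change, among those with adjusted p under 0.05, a mean of at least 1 CPM, from the recovered reads, and no overlap between the groups. The first 2 digits of an identifier starting with Os give the chromosome by the naming convention of the rice annotation, and the number after g runs along it.

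Alternatives fixed beforehand were median-ratio scaling, no filter, a filter at a mean of 1 CPM, only the groups compared in the fit, the replicate number as a covariate, a log2 change of at least 1, a pseudocount of 0.1, and each library left out in turn. The planned count-based tests were meant for deposited counts and were not run; the recovered reads were tested with voom alone. The tests by voom on the recovered reads, quantile normalization and identifiers starting with Os alone were chosen after seeing the data, as were the pseudocount of 0.1 for the named identifiers, the Fisher's exact tests by chromosome and kind of identifier and the division by mean FPKM. Fisher's exact test takes genes as independent. Genes measured in the same libraries are not, so its p-values may be too small. Overlaps between comparisons that share the WT libraries were set beside 20 simulated data sets of unchanged groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.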

Results

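Gene expression in rice leaf primordia, the young leaves at the shoot apex, was compared between WT and lines labelled as mutants of auxin transport components. Loss of these components was not checked in the data. OsPIN1c and OsPIN1d are PIN proteins, carriers that export auxin from cells, and OsPID is a protein kinase of the PINOID type, which phosphorylates PIN proteins. The 12 libraries comprised 3 each of WT, ospin1c ospin1d, ospid C1 and ospid C2, and held 15211547 to 16422849 reads. Between 26178 and 27194 identifiers had a value above 0. The lowest correlation between libraries of a group was 0.960, in ospid C2.

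The first principal component held 35.3% of the variance and set the 6 ospid libraries, at 6.79 to 56.4, apart from WT and ospin1c ospin1d, at -38.3 to -27.7. The second placed WT at 21.1 to 33.9 and ospin1c ospin1d at -45.1 to -30.4. Replicate 1 of ospid C2, at 6.79 on the first component, was the ospid library nearest to WT.

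**Figure D1:**
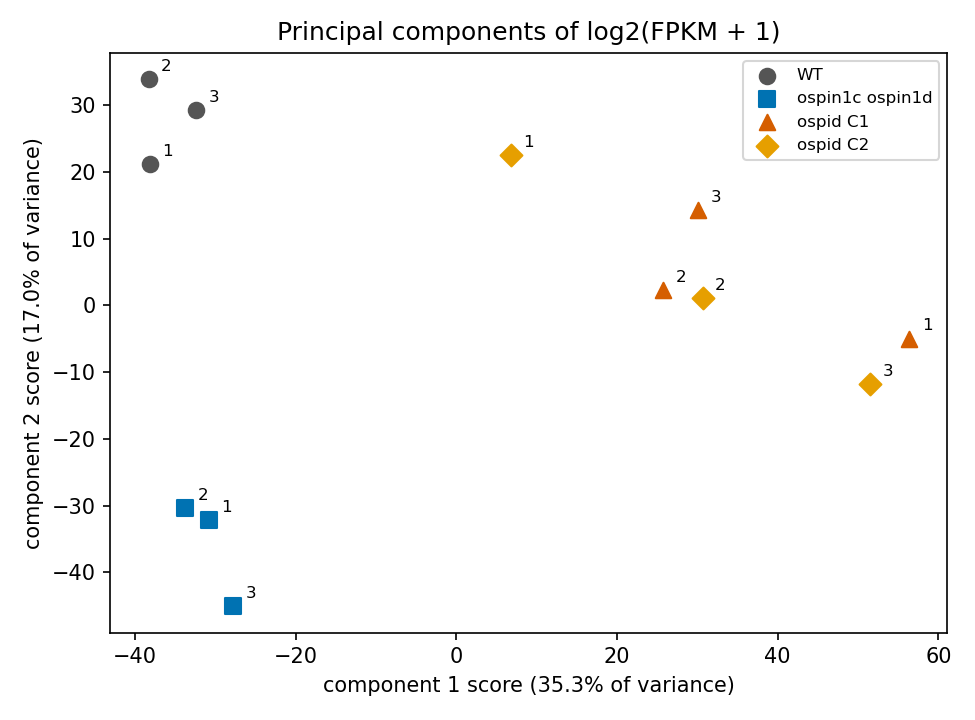
Scores of the 12 libraries on the first and second principal components of log2(FPKM + 1); each point is a library, its symbol the group and its number the replicate. The ospid libraries lie at 6.79 or above on the first component and all others at -27.7 or below.

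The comparison of ospin1c ospin1d with WT asks what differs in plants labelled as mutant for both PIN carriers. EPlOSAG00000008100, a feature of at least 86 bases, stood at 225, 342 and 308 FPKM in the ospin1c ospin1d libraries and was listed at 0 in the other 9 (adjusted p = 4.25e-11). EPlOSAG00000008091, of at least 29 bases, stood at 218, 238 and 246 FPKM there, from 99, 107 and 116 recovered reads. It was also listed at 0 in the other 9 (adjusted p = 4.19e-12). By limma with only these 2 groups in the fit its adjusted p was 4.45e-07, and by voom on the recovered reads 1.66e-06. Os08g0330800 was at 53.5 ± 1.75 FPKM in WT (SD, n = 3), 45.5 ± 6.32 in ospid C1 and 50.5 ± 8.13 in ospid C2, and was listed at 0 in all 3 ospin1c ospin1d libraries (adjusted p = 1.99e-10). Os08g0332100 fell from 48.9 ± 13.4 FPKM in WT to 0, 0 and 0.0787 FPKM, a log2 change of -5.57 (SE 0.177, adjusted p = 4.48e-09). In all, 490 of 21250 genes changed, 281 up and 209 down, and 291 of them by at least 1 on the log2 scale. Falls were more frequent on chromosome 8, with 35 of 1327 tested genes (2.64%) against 0.901% elsewhere (Fisher's exact test, two-sided, adjusted p = 1.77e-05 over 96 tests). They were not spread evenly along it: 9 lay in a stretch of 52 tested genes and 5 in another of 43, described under other observations. The count was 322, 304 and 203 without WT replicates 1, 2 and 3, 241, 227 and 185 without ospin1c ospin1d replicates 1, 2 and 3, and 788 without ospid C2 replicate 1. Rises no longer outnumbered falls without ospin1c ospin1d replicate 2 (111 up, 116 down) or replicate 3 (80 up, 105 down).

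The first OsPID line, ospid C1, was compared with WT to see what differs in a line labelled as mutant for the kinase. Os01g0537250 rose from 0, 0 and 0.154 FPKM in WT to 357 ± 44.0 FPKM (SD, n = 3), a log2 change of 8.41 (SE 0.217, adjusted p = 2.01e-09). Os03g0115800 was listed at 0 in all WT libraries and stood at 309 ± 10.8 FPKM in ospid C1 (adjusted p = 0.000141). Voom on the recovered reads gave an adjusted p of 0.0236. In ospin1c ospin1d this identifier stood at 66.2, 49.3 and 3.30 FPKM, also above WT (adjusted p = 0.00812). EPlOSAG00000002468, of at least 56 bases, was at 225, 84.2 and 116 FPKM in WT and listed at 0 in ospid C1 (adjusted p = 3.80e-05). Os01g0520180 was at 29.1 ± 7.92 FPKM in WT and listed at 0 in ospid C1 (adjusted p = 1.09e-07). In all, 3293 genes changed, 2166 up and 1127 down. Among genes of 5 to 20 FPKM on average, 12.9% rose and 5.09% fell, and among those of 100 FPKM or more, 7.46% rose and 13.7% fell. The median log2 change of all tested genes was 0.15 as deposited and 0.02 with median-ratio scaling, which called 1352 up and 1785 down, so the share that rose went from 65.8% to 43.1%, and quantile normalization called 1377 up and 1544 down; 2479 genes were called under both scalings. The count was 1232, 1757 and 1697 without WT replicates 1, 2 and 3, 933 and 1817 without ospid C1 replicates 1 and 3, and 1808 with only these 2 groups in the fit. Rises numbered 3299 without ospid C2 replicate 1 and 1333 without ospid C2 replicate 2.

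The second OsPID line, ospid C2, was compared with WT in the same way. The same 4 identifiers met the naming rule. Os01g0537250 reached 388 ± 26.3 FPKM (SD, n = 3; log2 change 8.53, SE 0.217, adjusted p = 1.71e-09) and Os03g0115800 329 ± 36.4 FPKM (adjusted p = 0.000119). EPlOSAG00000002468 (adjusted p = 3.62e-05) and Os01g0520180 (adjusted p = 1.09e-07) were listed at 0 in all 3 libraries. In all, 2128 genes changed, 851 up and 1277 down. Falls were less frequent on chromosome 11, with 33 of 1016 tested genes (3.25%) against 6.60% elsewhere (Fisher's exact test, two-sided, adjusted p = 0.000249 over 96 tests). Features starting with EPlOSAG were called less often in both directions by Fisher's exact test, two-sided, over 20 tests. Of 1608, 0.871% fell against 6.43% of the other identifiers (adjusted p = 9.57e-27), and 2.61% rose against 4.12% (adjusted p = 0.00381). The same test gave this in ospid C1, where 1.24% fell against 5.64% (adjusted p = 2.55e-18) and 5.29% rose against 10.6% (adjusted p = 6.28e-13). The mean of the ospid lines against ospin1c ospin1d also showed it. For ospin1c ospin1d against WT the threshold was not passed (adjusted p = 0.105 for rises and 0.114 for falls). Whether read numbers account for the difference was not tested. The count was 1363 and 1352 without WT replicates 1 and 3, 3427, 1230 and 1072 without ospid C2 replicates 1, 2 and 3, and 1058 with only these 2 groups in the fit. Without ospid C2 replicate 1 rises outnumbered falls, with 2050 up and 1377 down, and without WT replicate 2 rises numbered 413.

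**Figure D2:**
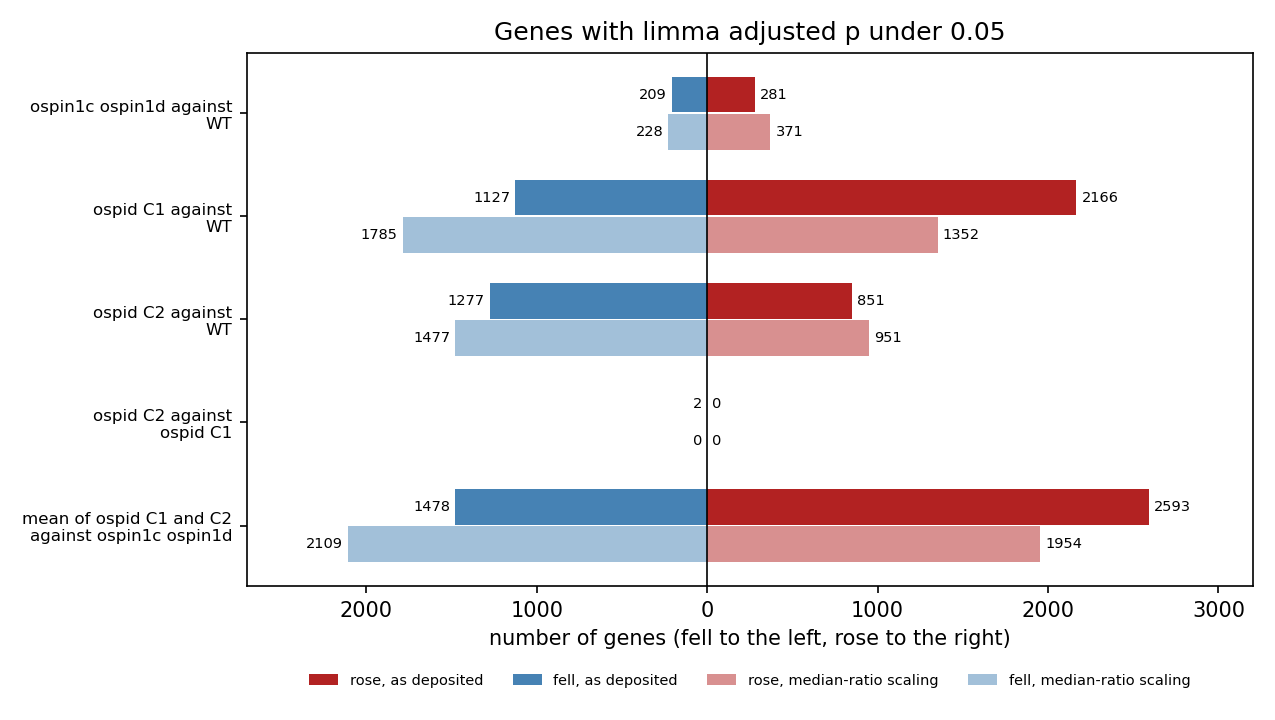
Number of genes with limma adjusted p under 0.05 that rose (right) or fell (left) in each comparison, with FPKM as deposited (dark) and after median-ratio scaling (light). For ospid C1 against WT the counts are 2166 up and 1127 down as deposited and 1352 up and 1785 down after scaling.

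The ospid lines were compared with each other, since both carry the same genotype label. By limma 2 genes differed, both lower in ospid C2, while 2223 had an unadjusted p under 0.05. A share of 0.05 of unchanged genes passes that bound by chance. The median log2 difference of all tested genes was -0.0941 as deposited and -0.00876 with median-ratio scaling. Whether this shift accounts for part of the 2223 was not tested. Neither met the naming rule, and both are given because the count is small, after their values were seen. Os06g0591551 was at 2.68 ± 0.429 FPKM in ospid C1 and 0.265 ± 0.266 in ospid C2 (SD, n = 3), or 9.67 and 1 reads per library (adjusted p = 0.0467). EPlOSAG00000053066 had 1 read in each ospid C1 library and none in ospid C2 (adjusted p = 0.0450). Median-ratio scaling and voom called 0 genes. The count was 1 without WT replicate 1 or ospin1c ospin1d replicate 1, 6 without WT replicate 2, 42 without ospid C2 replicate 2, and 0 without any other single library.

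The mean of both ospid lines was set against ospin1c ospin1d to test directly whether these mutants differed. The labels name no separate lines of ospin1c ospin1d. Loss of the carriers thus cannot be told apart from other traits of that line. Os01g0537250 was at 373 ± 36.5 FPKM in the ospid lines (SD, n = 6) and at 0, 0.0542 and 0.979 FPKM in ospin1c ospin1d, a log2 difference of 8.19 (SE 0.188, adjusted p = 1.53e-10). Os03g0629800 was at 130 ± 12.6 FPKM in the ospid lines (SD, n = 6) and at 0, 0.303 and 0.577 FPKM in ospin1c ospin1d, a log2 difference of 6.68 (SE 0.130, adjusted p = 3.92e-11), and was listed at 0 in WT. EPlOSAG00000008100 (adjusted p = 8.30e-12) and EPlOSAG00000008091 (adjusted p = 8.16e-13) were listed at 0 in the ospid lines. In all, 4071 genes differed, 2593 higher and 1478 lower in the ospid lines, while at a log2 difference of at least 1 the balance was the other way, with 295 higher and 433 lower. Higher values were more frequent on chromosome 8, with 217 of 1327 genes (16.4%) against 12.6% elsewhere. They were also more frequent on chromosome 11, with 171 of 1016 genes (16.8%) against 12.6% (Fisher's exact test, two-sided, adjusted p = 0.00328 for each, over 96 tests). By the same test, rises against WT showed no such excess on chromosome 8. They were 11.3% against 10.5% in ospid C1 (adjusted p = 0.718) and 4.37% against 4.10% in ospid C2 (adjusted p = 0.858). The chromosome 8 result shares the ospin1c ospin1d libraries with the falls reported above. Median-ratio scaling called 1954 higher and 2109 lower, so the share that was higher went from 63.7% to 48.1%. Quantile normalization kept the deposited direction, with 2483 higher and 1908 lower. Under both the deposited and the median-ratio scaling, 3429 genes were called. The count was 2119, 1448 and 1973 without ospin1c ospin1d replicates 1, 2 and 3, and 3964 genes were higher without ospid C2 replicate 1 and 1606 without ospid C2 replicate 2.

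**Figure D3:**
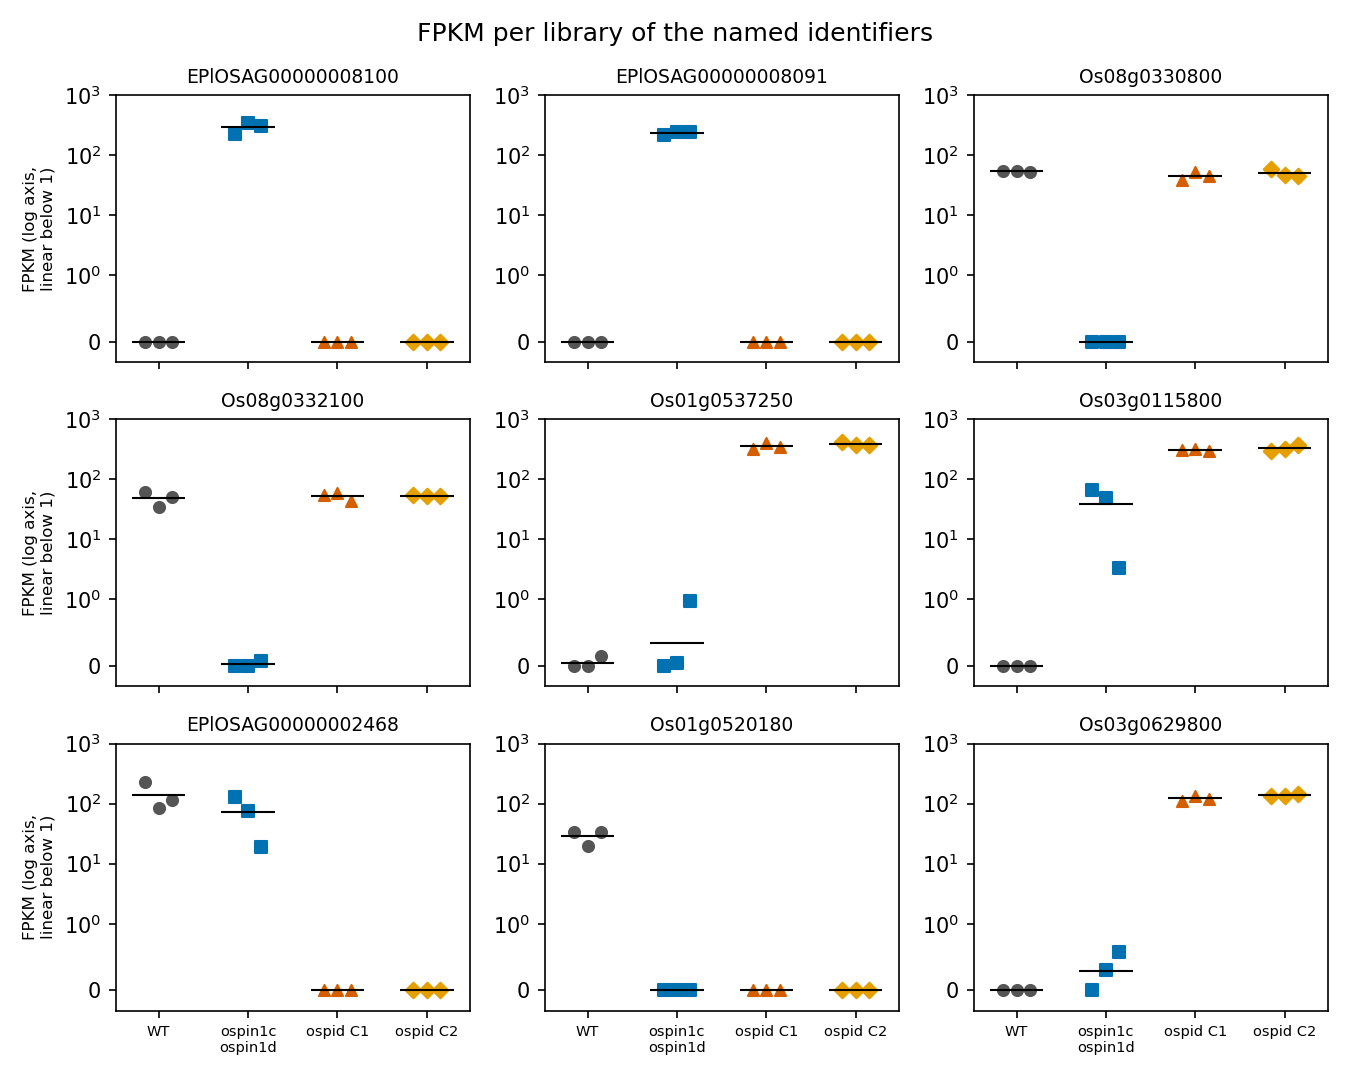
FPKM of the 9 identifiers named by the rule in each of the 12 libraries, on an axis that is logarithmic above 1 and linear below; points are libraries and lines group means. Os01g0537250 stands at 357 and 388 FPKM on average in ospid C1 and ospid C2, and Os08g0330800 is listed at 0 in ospin1c ospin1d alone.

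Calls were then compared across the mutants. Between ospid C1 and ospid C2, 675 genes rose in both and 659 fell in both, against 86.7 and 67.7 for independent lists, and 0 were called in opposite directions. Between ospin1c ospin1d and ospid C1, 116 rose in both and 59 fell in both, against 28.6 and 11.1; 2 rose in the first and fell in the second, and 9 did the reverse. Between ospin1c ospin1d and ospid C2, 113 rose in both and 66 fell in both, against 11.3 and 12.6, with 0 and 2 calls in opposite directions. All 3 mutant lines shared 92 rises and 48 falls, among them Os01g0520180, which was listed at 0 in every mutant library. Simulated unchanged groups set against the same WT libraries gave 0 shared calls, a value that holds for groups with no effects and not for lists of changed genes. Across genes, which are not independent replicates, the log2 changes of ospid C1 and ospid C2 correlated at r = 0.835 (rho = 0.807) with a covariance of 0.241, against 0.499 and 0.0308 in the simulation. For ospin1c ospin1d the correlation was 0.400 (rho = 0.351) with ospid C1 and 0.445 (rho = 0.434) with ospid C2, below the simulated 0.502 and 0.498, while the covariances of 0.0986 and 0.109 lay above the simulated 0.0311 and 0.0308. The log2 changes of ospin1c ospin1d had the same sign as those of ospid C1 for 59.7% of genes and of ospid C2 for 63.2%. Both shares lay below the simulated 66.6%. Between the ospid lines the share was 81.8%, above the simulated 66.6%. WT had 3 libraries and could not be split into parts of at least 2, so part of each excess may come from the shared controls.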

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

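Each identifier named in the report was looked at again where the effects of the mutant lines differed by a direct limma test. The mean of the ospid lines differed from ospin1c ospin1d on the log2 scale by -8.17 for EPlOSAG00000008100 and -7.87 for EPlOSAG00000008091, which were listed at 0 outside ospin1c ospin1d. It differed by 5.60 for Os08g0330800 and 5.71 for Os08g0332100, which were at or near 0 in ospin1c ospin1d alone. The difference was 8.19 for Os01g0537250 and 6.68 for Os03g0629800, at or near 0 outside the ospid lines, and 3.71 for Os03g0115800, which ospin1c ospin1d also expressed. It was -5.85 for EPlOSAG00000002468, which was listed at 0 in the ospid lines. The values for the low identifiers were 0.69 for EPlOSAG00000053066 and -0.90 for Os06g0591551. Between the ospid lines, ospid C2 differed from ospid C1 by -1.38 for EPlOSAG00000053066 and by -1.56 for Os06g0591551.

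Whether other groupings of the same libraries give as many calls was a test set before its result was seen. With 6 libraries in the fit there are 10 splits, too few for a share under 0.05. The real split called 620 genes for ospin1c ospin1d against WT and the highest other split 3; for ospid C1 against WT the numbers were 1808 and 1, for ospid C2 against WT 1058 and 0, and for ospid C2 against ospid C1 1 and 0. For the mean of the ospid lines against ospin1c ospin1d, the splits pooled the ospid libraries into a single group. In that fit the real split called 3004 genes, against 4071 in the main fit. It was the only 1 of 84 splits to reach that count, and the highest other gave 7. Chance assignment of single libraries is thus argued against as the source of that count. Splits that mix lines add the differences between lines to the spread, so the test cannot separate genotype from line.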

How the results depend on the processing

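The voom, quantile and Os-identifier tests, and for named identifiers the pseudocount of 0.1, were chosen after seeing the data. Of 348 results for named identifiers under alternatives, 348 kept their direction and 319 their side of the threshold. The results that lost it were those of the 2 identifiers that differed between ospid C2 and ospid C1. Identifiers filtered out in a setting gave no result there. EPlOSAG00000008100 and EPlOSAG00000008091 had none with any ospin1c ospin1d library left out. Os01g0520180 had none with any WT library left out, and EPlOSAG00000053066 none with any ospid C1 library left out. Identifiers named by the rule were picked for large changes without overlap, which favours a kept direction. The count of changed genes moved by more than 1.5 times as follows. For ospin1c ospin1d against WT (490) it was 325 with the replicate block and 291 at a log2 change of at least 1. For ospid C1 against WT (3293) it was 2189 without a filter, 1808 with only the groups compared, 2141 with the replicate block and 829 at a log2 change of at least 1. For ospid C2 against WT (2128) it was 1058 with only the groups compared and 862 at a log2 change of at least 1. For ospid C2 against ospid C1 (2 by limma, 2223 at an unadjusted p under 0.05) it was 0 with median-ratio scaling, with a mean of 1 CPM, with a pseudocount of 0.1, with voom and with quantile normalization, 1 with only the groups compared, 5 without a filter and 7 for identifiers starting with Os. For the mean of the ospid lines against ospin1c ospin1d (4071) it was 728 at a log2 change of at least 1. The stricter fold threshold lowers counts by construction; the cause was not tested for the others. Leaving out each library in turn gave 185 to 788, 933 to 4716, 1072 to 3427, 0 to 42 and 1448 to 5618 in the same order of comparisons. Calls shared in direction went from 175 to 87 for ospin1c ospin1d with ospid C1, from 179 to 89 with ospid C2 and from 1334 to 475 between the ospid lines at a log2 change of at least 1, and the correlation between the ospid lines from 0.835 to 0.871 over genes of at least 1 CPM.

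The replicate numbers did not pair the samples. Over 18 pairs with the same number the correlation of deviations from group means was -0.227 to 0.0694. Of 12 libraries, 0 matched their own number best. The replicate block lowered the count for ospin1c ospin1d against WT from 490 to 325. It lowered that for ospid C1 against WT from 3293 to 2141, and changed the other counts by less than 1.5 times. The planned tests on counts, and the alternatives for gene sets and targeted genes, were not run. Depth limits low features: a difference of 1 read per library, as for EPlOSAG00000053066, is within counting error of 0.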

Other observations

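The scan along the chromosomes and the tests on switched genes, on ospid C2 replicate 1 and on abundant genes were chosen, in the form given here, after results were seen; the bounds on gene length were set before. Identifiers starting with Os were grouped into windows of 20000 identifier units with at least 10 tested genes, and falls and rises of each mutant line against WT were counted per window by a hypergeometric test. This test also takes genes as independent. Of 1932 tests, 5 passed an adjusted p of 0.05, all for falls in ospin1c ospin1d. On chromosome 8, 9 of 52 tested genes fell between 400000 and 419999 (adjusted p = 4.79e-06) and 5 of 43 between 320000 and 339999 (adjusted p = 0.0354), the window of Os08g0330800 and Os08g0332100. On chromosome 11, 6 of 18 fell between 680000 and 699999 (adjusted p = 1.68e-05). On chromosome 4, 6 of 32 fell between 360000 and 379999 (adjusted p = 0.000484) and 4 of 25 between 120000 and 139999 (adjusted p = 0.0431). Most tested genes of these windows were not called as fallen.

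A set of 66 genes was switched, at 3 FPKM or more in every library of a genotype and at 0.3 FPKM or less in every library of another. Of these, 12 were on in ospin1c ospin1d alone, 11 were off in ospin1c ospin1d alone, 5 were on in both ospid lines alone and 3 were on in WT alone. Chance loss of reads is argued against as the source of the whole set, since 100 random regroupings of the libraries gave a median of 5 such genes and at most 36. Among the 47 with a chromosome in the identifier, 5 pairs lay within 2000 identifier units, against 0.853 on average in 10000 random sets of equally expressed genes, of which 21 reached 5. Genes switched between ospin1c ospin1d and ospid C1 made 5 pairs, reached by 0 of the random sets, and those switched between ospin1c ospin1d and WT made 2, reached by 225. Those switched between WT and ospid C1 or ospid C2 made 1 pair each, reached by 668 and 1138 sets, and the difference between these comparisons was not tested. A candidate explanation is stretches of sequence that differ between the lines, though regulation shared by neighbours would give the same pairs. Loss of OsPIN1c, OsPIN1d or OsPID alone stays open: 1 gene was switched between ospid C1 and ospid C2, which a common ancestor plant predicts as well as a shared genotype.

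Replicate 1 of ospid C2 lay nearer to WT than the other ospid C2 libraries, and its deviation from them correlated at -0.412 across genes with the difference between ospid C1 and WT. The value of 0.410 for ospid C2 replicate 3 is not separate evidence, since deviations within a group sum to 0, and this measure does not tell which of these libraries stands apart. As a mixture, replicate 1 would need 23.0% WT RNA. The 6 genes on in WT and off in ospid C1 and the other ospid C2 libraries would then be at a median of 4.22 FPKM, but the highest was at 0.0992 and the median ratio of observed to needed level was 0, which argues against WT RNA in this library. Its depth of 16422849 reads, the highest of the 12 libraries, argues against shallow sequencing. A difference in the stage or make-up of the sampled tissue was not tested and stays open.

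The median gene was higher in ospid C1 than in WT by 0.15 on the log2 scale. Over the tested genes other than the 100 most abundant, rescaling each library by its remaining reads took the difference from 0.152 to 0.128, or 84.4% of its size, and 79.7% to 88.4% with a WT or ospid C1 library left out. Those genes thus account for a part at most, and since the lowest value lies under the bound of 80% set for excluding them, their role stays open. Rescaling to equal FPKM sums instead gave 109%, but it also changes the weight of gene length and decides nothing. The difference correlated with gene length at a Spearman rho of 0.185 across genes, between the bounds set beforehand, so a bias by gene length cannot be told apart from a change in expression. No biological explanation was tested.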
